A study of Mus musculus with 2 samples.

How the data were processed

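Small peritoneal macrophages were sorted from 5-week-old male SWISS mice, an outbred stock, after an intraperitoneal injection of 20 mg/kg lipopolysaccharide (LPS) from Escherichia coli, which produces endotoxemia. Per the labels' protocols, the mice received 30 mL/kg saline under the skin 6 h after LPS and were killed 22 h after LPS. The second group also received 0.3 mg/kg LCC-12 into the peritoneum 6 h after LPS. LCC-12 is known as a compound that targets copper in mitochondria. Each group was a single library made from pooled cells, 102283 cells from 7 mice for LPS and 66967 cells from 8 mice for LPS+LCC-12. No library of mice without LPS was analysed here.

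Per the labels' protocols, 10 ng of total RNA per group was fragmented at 94 °C for 4 minutes and converted to libraries with a stranded kit for low input, with depletion of ribosomal cDNA and 12 cycles of PCR. The libraries were sequenced as pairs of 100 bp reads with a target of 100 M clusters each. The molecule field of the labels names polyA RNA, whereas the extraction protocol describes total RNA with ribosomal depletion, and the protocol was followed here. The deposited values are raw counts per gene, whole numbers that were not normalized, in 1 table with a column per library. The aligner STAR and the genome build mm10 are named per the submitters' processing notes, without a version of the aligner. The counting tool, its use of strand and the gene annotation are not given in the sources used here. Antisense and overlapping genes, and near-identical copies such as Ifit3 and Ifit3b or Hspa1a and Hspa1b, are therefore uncertain where reads could be shared.

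Gene symbols, biotypes and coordinates were taken from GENCODE M21 on GRCm38 (mm10) by gene ID. Of 55487 IDs in the table, 55394 matched, and the other 93 held 304 counts in the LPS library and 325 in the LPS+LCC-12 library. No row without a gene was present. The columns were tied to groups by the library codes in the labels.

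The counts were scaled with edgeR 4.0.16 (TMM) in R 4.3.3, and 0.5 counts were added per library in proportion to its scaled size. The log2 ratio is the LPS+LCC-12 library over the LPS library. With 1 library per group there was no test, and no p-value, standard error or call of changed genes is given. Differences compare these 2 libraries and have no replicate check. A gene was counted as higher or lower when it differed by at least 2-fold and had 50 or more counts in the higher library. Each ratio has an exact 95% interval from the binomial split of its counts (Clopper-Pearson), and each share of counts an exact binomial interval. List medians have 95% intervals from 1000 Poisson redraws of the counts. These intervals cover counting error only, because PCR copies are not independent molecules and differences between pools of mice are not measured. For a gene with 0 counts in 1 library, the fold is given against a floor of 3 counts in that library. Its log2 ratio has the 0.5 added counts of the other genes. Its counting interval can begin at a smaller fold, so the fold against the floor is not a lower bound.

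Genes were grouped in 28 pathway lists and 16 cell type marker lists. All but 1 of 1019 list entries matched a gene, 1 of them through a RefSeq synonym; Ahsp did not match. Members with 50 or more counts in the higher library were summarised by their median log2 ratio. The median's percentile was taken among 10000 random lists of the same size, matched on mean expression in 20 bins, and is a description of these libraries. A list with at least 5 such members was said to stand apart below percentile 2.5 or above 97.5. Random lists fall there 5% of the time, but genes that vary together between any pair of pools do so more often. Some genes are in more than 1 list: the small peritoneal macrophage list shares 5 genes with the MHC class II list and 4 with the alternative activation list.

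The named genes followed a rule. They were the 15 highest and 15 lowest genes past the 2-fold rule by the interval bound nearest 0, leaving out predicted genes and symbols marked as pseudogenes. In each list up to 4 members past the rule with the largest ratios were taken, or the 2 members with the most counts where none passed. A further 16 genes were always taken: Il6, Tnf, Il1b, Il10, Nos2, Ccl2, Cxcl10, Arg1, Cd44, Slc31a1, Mt1, Mt2, Gata6, Adgre1, Ccr2 and S100a9. Some genes that the rule takes are not reported here. The lists, the rules and most alternatives were fixed before the data were examined.

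The alternatives were scaling by total counts, by DESeq2 1.42.0 median of ratios, by the upper quartile, and by totals without the 100 most abundant and mitochondrial genes. Other alternatives were count minimums of 1, 10 and 200, 5 added counts, thinning the deeper library, size limits of 1.5-fold and 3-fold, the whole interval beyond 2-fold, list means, 10 bins and random lists without listed genes. Counts of protein-coding genes only, and the interferon list relative to the neutrophil list, were added after seeing the data. Leaving out a replicate was not possible. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the intervals, lists and plots.

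The calculation was tested on simulated data for all 55487 genes. With counting error alone, the rule recovered 49 of 50 genes changed 2.5-fold and all 50 changed 3-fold, and 1 of 12927 unchanged genes passed it. With an assumed biological coefficient of variation between pools of 0.2, it recovered 31 of 50 genes changed 2.5-fold and 45 of 50 changed 3-fold, and 322 of 13024 unchanged genes passed. With 0.3 it recovered 36 and 39 of 50, and 1639 of 13090 unchanged genes passed. With 0.4 it recovered 34 and 35 of 50, and 3218 of 13156 unchanged genes passed. In the data 1436 of 13482 genes passed, 10.65%. Of the unchanged genes, 2.47% passed when simulated at 0.2, 12.5% at 0.3 and 24.5% at 0.4. The quartiles of the log2 ratios in the data were -0.27 and 0.26. The simulation gave every gene the same variation, so these shares do not tell how many of the 1436 genes passed by chance. The true variation between pools is not known. The median half-width of the counting interval was 0.58 on the log2 scale for genes with 50 to 100 counts in the higher library, 0.24 for 100 to 1000, and 0.083 for 1000 to 10000.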

Results

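RNA was sequenced from small peritoneal macrophages, a macrophage population of the abdominal cavity, sorted from mice with LPS endotoxemia. One library came from 7 mice given LPS alone and the other from 8 mice given LPS and then LCC-12. The deposited gene counts summed to 50618409 in the LPS library and 47721888 in the LPS+LCC-12 library. At least 1 count was present for 24376 and 22879 genes, and 50 or more for 13102 and 12765 genes, respectively. With 1 library per group there were no replicates, so every difference given is between these libraries and was not tested against variation between mice.

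The comparison asked how the transcripts of these macrophages differed when LCC-12 was given during endotoxemia. At least 2-fold lower in the LPS+LCC-12 library were 31 of 48 interferon-stimulated genes, 10 of 15 neutrophil markers and 12 of 36 cytokine and chemokine genes. At least 2-fold higher were 11 of 15 markers of small peritoneal and monocyte-derived macrophages, 11 of 20 of large peritoneal macrophages, 5 of 11 MHC class II genes and 11 of 25 alternative activation genes, and 2 others of the last list were at least 2-fold lower. Among 13482 genes with 50 or more counts in the higher library, 540 were at least 2-fold higher with LCC-12, 896 were at least 2-fold lower and 12046 were within 2-fold. At least 4-fold differences were seen for 110 higher and 184 lower genes. The median log2 ratio over these genes was 0.02. Of 11220 protein-coding genes, 428 were higher and 500 lower. Of 312 lincRNA genes, 88 were lower and 18 higher, and of 269 genes classed as antisense, 78 were lower and 13 higher. Of 67 snoRNA genes, 2 were lower and 0 higher. The 2-fold counts moved by over 1.5 times with the count minimum and the size limit.

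Ranked by the interval bound nearest 0, with predicted genes left out, the first gene in the higher direction was Dmpk, a protein kinase gene known from myotonic dystrophy (chromosome 7, 19083849 to 19093821, GRCm38). It had 28 counts with LPS and 1148 with LPS+LCC-12, a log2 ratio of 5.38 (interval 4.86 to 6.00). Cd5l, a secreted scavenger protein of tissue macrophages (chromosome 3, 87357881 to 87371073), had 466 and 10022 counts and was 22.2-fold higher (log2 ratio 4.47, 4.34 to 4.61). Timd4, a phosphatidylserine receptor of resident macrophages (chromosome 11, 46810800 to 46844332), was 16.4-fold higher (log2 ratio 4.03, 3.87 to 4.21). Dpysl3 was 14.6-fold higher with 368 and 5202 counts, and Fcrls, an Fc receptor-like gene of macrophages, was 9.90-fold higher with 99 and 954 counts. Ank2, Plxna4 and Itih1 were 13.9-fold, 12.1-fold and 15.6-fold higher, with 31, 40 and 10 counts in the LPS library. Rps3a3, annotated as a processed pseudogene whose reads can be shared with its parent gene, had 15 and 579 counts. Arsi had 0 counts with LPS and 100 with LPS+LCC-12, 34.4-fold higher against the floor of 3 counts, with a log2 interval from 4.78. Tspan18 had 0 and 67 counts, 23.1-fold higher against that floor, with a log2 interval from 4.19. Ttc34, Ramp3, Rgs7bp and Clrn3 had 1 or 2 counts with LPS, and their log2 ratios were 5.36 (3.78 to 8.74), 5.61 (3.67 to 11.52), 4.98 (3.39 to 8.37) and 5.32 (3.37 to 11.23).

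In the lower direction, the first gene by the same ranking was Col6a3, a chain of collagen VI, with 490 counts with LPS and 2 with LPS+LCC-12 (log2 ratio -7.57, -10.94 to -6.03). Igha, the constant region of IgA, had 174 counts and 1 count (log2 ratio -6.82, -12.71 to -4.90). The heavy-chain variable gene Ighv1-55 had 70 and 4 counts. The epithelial keratins Krt8 and Krt18 had 101 and 3 counts and 54 counts and 1 count, with log2 ratios of -4.82 (-7.33 to -3.44) and -5.14 (-11.04 to -3.17). Plekhs1 had 54 counts with LPS and 0 with LPS+LCC-12, 17.4-fold lower against the floor of 3 counts, with a log2 interval up to -3.78. The interferon-induced genes Ifit3, Ifit2 and Ifit3b were 10.9-fold, 7.81-fold and 7.08-fold lower. Ifit3 lies on chromosome 19 from 34583531 to 34588731. Dnah8, a dynein heavy chain, was 7.15-fold lower, from 6515 to 882 counts. Steap4, a metalloreductase of iron and copper (chromosome 5, 7960457 to 7982213), had 24236 and 3531 counts and was 6.65-fold lower (log2 ratio -2.73, -2.78 to -2.68). Col1a2 had 126 and 11 counts, and Pkhd1l1, Apol9b and Ptprf had 84, 61 and 58 counts with LPS against 2, 1 and 3 with LPS+LCC-12. The log2 ratios of Pkhd1l1, Apol9b and Ptprf were -5.04 (-8.42 to -3.45), -5.32 (-11.21 to -3.35) and -4.02 (-6.55 to -2.61).

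**Figure D1:**
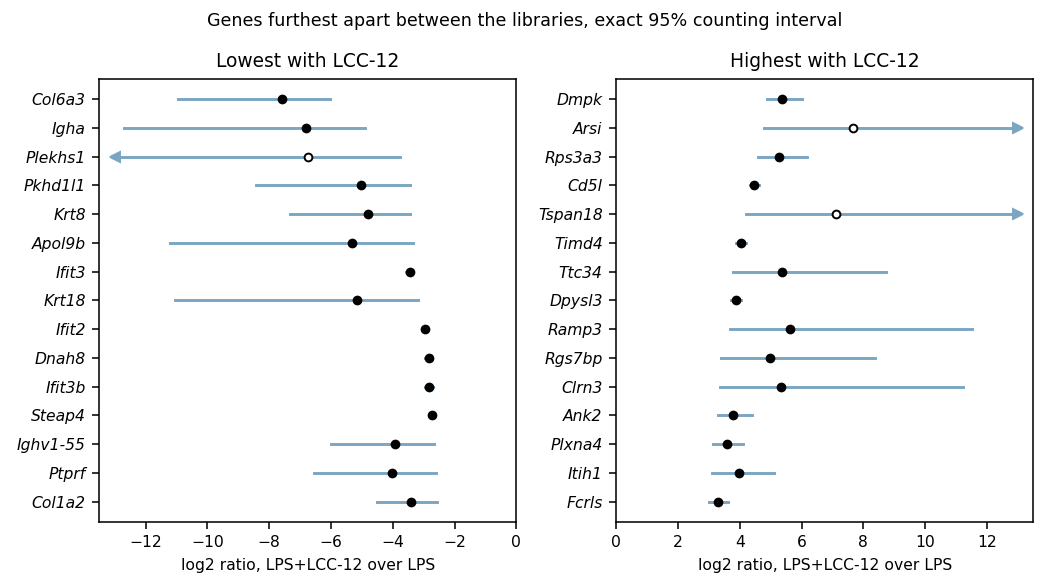
Log2 ratio of TMM-scaled counts, LPS+LCC-12 library over LPS library, for the 15 lowest and 15 highest genes by the rule (points) with exact 95% counting intervals (lines). Open points are genes with 0 counts in 1 library, whose interval has no outer end (arrow), and the intervals of Ifit3 and Cd5l are much narrower than that of Igha, which has 1 count with LPS+LCC-12.

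Interferon-stimulated genes, the antiviral program induced by interferons, had a median log2 ratio of -1.17 (-1.19 to -1.15) over 48 genes, the 0th percentile of random lists. Of these genes 31 were at least 2-fold lower, none was at least 2-fold higher and 17 were within 2-fold. Ifit1bl1 and Ifi44 were 8.11-fold and 7.52-fold lower, next to Ifit3 and Ifit2. Inflammatory cytokines and chemokines had a median of -0.83 (-0.87 to -0.73) over 36 genes, with 12 lower and 3 higher. The interferon-induced chemokines Cxcl11 and Cxcl10 were 6.03-fold and 4.03-fold lower, whereas Cxcl14 and Ccl24 were 6.60-fold and 6.14-fold higher. Il10, an anti-inflammatory cytokine, was 2.23-fold lower with 263 and 114 counts. Il1b, Ccl2 and Tnf were within 2-fold, with log2 ratios of -0.87 (-0.90 to -0.85), -0.95 (-0.98 to -0.92) and -0.64 (-0.71 to -0.58). Il6 had 936 and 969 counts, a log2 ratio of 0.10 (-0.03 to 0.23), a difference within counting error. Targets of NF-kB, a transcription factor of inflammation, had a median of -0.47 over 35 genes, with 6 lower and none higher. Among them Gadd45b was 3.01-fold lower, Nos2, the inducible nitric oxide synthase, 2.57-fold, Lcn2 2.35-fold and Tnip1 2.18-fold. The neutrophil marker list had a median of -1.14 in the same libraries and the monocyte list -0.60. Relative to the neutrophil median, in an alternative chosen after seeing the data, the interferon list had a median of -0.029. That subtraction would correct for neutrophils only if these transcripts came from neutrophils alone, which was not tested.

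Marker lists of both peritoneal macrophage types had medians above 0. The list of small peritoneal and monocyte-derived macrophages had a median of 1.78 (1.70 to 1.83) over 15 genes, with 11 at least 2-fold higher and none lower, at percentile 100. Cd226 was 6.27-fold higher, Retnla 6.34-fold and Cx3cr1, the fractalkine receptor, 5.05-fold. The list of large peritoneal macrophages had a median of 1.06 (0.99 to 1.15) over 20 genes, with 11 higher and none lower. Besides Cd5l and Timd4, Serpinb2 was 4.15-fold and Alox15 3.09-fold higher. Gata6, the transcription factor of large peritoneal macrophages, was within 2-fold with 529 and 720 counts (log2 ratio 0.49, 0.33 to 0.66). The general macrophage list had a median of 0.03 over 11 genes, all within 2-fold. In it Lyz2 and Ctss had log2 ratios of 0.56 and 0.03, and Adgre1, which encodes F4/80, had -0.02. Ccr2, a monocyte chemokine receptor, had -0.02 with 18229 and 17434 counts, the lowest ratio in the small peritoneal and monocyte-derived list.

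Genes of alternative activation and repair had a median of 0.53 over 25 genes, with 11 higher and 2 lower, at percentile 100. Cd36 and Cd163, scavenger receptors for lipids and for haptoglobin-bound hemoglobin, were 6.33-fold and 5.57-fold higher, whereas Arg1 was within 2-fold (log2 ratio 0.63, 0.62 to 0.65). MHC class II genes, which present antigen to CD4 T cells, had a median of 0.83 over 11 genes, with 5 higher and none lower. H2-Eb1 was 3.52-fold, H2-DMa 2.10-fold, H2-Ab1 2.05-fold and Cd74 2.04-fold higher. MHC class I genes had a median of -0.27 over 16 genes, all within 2-fold, and H2-D1 and Calr had log2 ratios of -0.45 and -0.08. The class I percentile of 0.74 passed 2.5 when means replaced medians. Among LXR targets, which include lipid efflux genes, 3 of 16 were higher, with a median of 0.25 at percentile 99.8. Lpl, a lipoprotein lipase, was 4.82-fold and Scd1 2.05-fold higher.

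**Figure D2:**
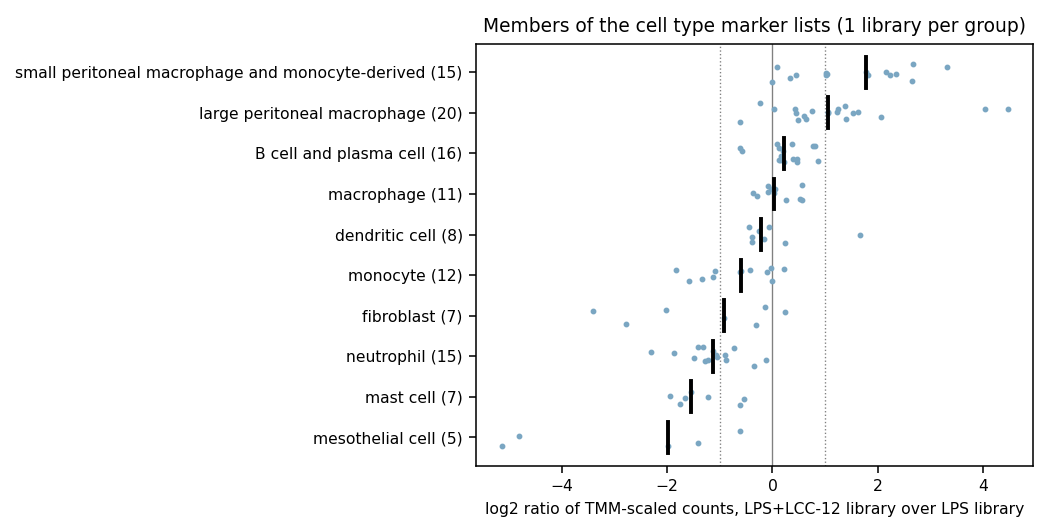
Log2 ratios of marker genes with 50 or more counts (points, LPS+LCC-12 over LPS) in each cell type list with at least 5 such genes, with the list median (bar) and the number of genes in parentheses. Dotted lines mark 2-fold, and the medians run from -1.99 for the mesothelial list to 1.78 for the small peritoneal macrophage list.

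Several marker lists of other cells that the sort could hold had medians below 0. Neutrophil markers had a median of -1.14 (-1.17 to -1.08) over 15 genes, with 10 lower, none higher and all below 0. Mmp8, a neutrophil collagenase, was 4.95-fold lower, Mrgpra2b 3.68-fold, Cxcr2 2.81-fold and S100a9, a subunit of calprotectin, 2.67-fold. S100a9 had a CPM of 3913 with LPS and 1464 with LPS+LCC-12. Monocyte markers had a median of -0.60 over 12 genes, with 5 lower and none higher, and Plac8, Chil3 and Ms4a4c were 3.55-fold, 2.52-fold and 2.19-fold lower. Mast cell markers had a median of -1.54 over 7 genes, with 5 lower. Tpsb2, Kit, Hdc and Cma1 were 3.85-fold, 3.39-fold, 3.17-fold and 2.91-fold lower. Their counts with LPS were 85, 316, 9855 and 160, and whether the Hdc counts came from mast cells was not tested. Mesothelial markers had a median of -1.99 over 5 genes, with 4 lower, among them Upk3b and Krt19 besides Krt8 and Krt18. Fibroblast markers had a median of -0.91 over 7 genes, with 3 lower, namely Col1a2, Col1a1 and Col3a1 at 10.7-fold, 6.85-fold and 4.04-fold. The mesothelial and fibroblast percentiles of 0.29 and 0.18 became 27.3 and 13.9 with a minimum of 200 counts. Over all settings, with list means included, the values of these lists ran from -2.80 to -0.62 and from -1.46 to -0.32.

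B cell and plasma cell markers had a median of 0.21 over 16 genes, all within 2-fold, at percentile 93.7. Ighm and Igkc, constant regions of the antibody chains, had log2 ratios of 0.13 and 0.38. Dendritic cell markers had a median of -0.21 over 8 genes, at percentile 24.8, with Ccl22 3.15-fold higher. Fewer than 5 genes could be read in the remaining marker lists. T cell markers had 2 such genes, Il7r and Cd3d, with log2 ratios of -0.16 and -0.87. NK cell markers had 3, with Gzmb 2.55-fold lower. Eosinophil markers had 3, with Alox15 higher. Platelet markers had 4, of which Itgb3 and Tubb1 were 2.73-fold and 2.60-fold lower and Pf4 2.57-fold higher. Endothelial markers had 1, Cdh5, with a log2 ratio of 0.95 (0.32 to 1.61), and Tie1 had 27 and 35 counts. No erythroid marker reached 50 counts, and Hbb-bs had 24 and 15 counts and Hba-a1 17 and 11.

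Genes of copper handling did not stand apart as a list, with a median of -0.04 (-0.13 to 0.04) over 23 genes at percentile 20.6. Steap4 and Prnp, the prion protein that binds copper, were lower, Prnp by 2.48-fold, and Steap3 was 2.71-fold higher. The copper importer gene Slc31a1 had 2424 and 2284 counts (log2 ratio -0.04, -0.12 to 0.04), a difference within counting error. The metallothionein genes Mt1 and Mt2 had log2 ratios of -0.19 (-0.25 to -0.13) and -0.54 (-0.59 to -0.49). Cd44, whose product takes up hyaluronan, had 0.21 (0.20 to 0.23). Iron handling genes had a median of 0.02 over 22 genes, with 2 higher and 2 lower. Fth1, the ferritin heavy chain, was 2.40-fold lower with 343533 and 138793 counts, Lcn2 was lower, and Cd163 and Hfe were higher, Hfe by 2.01-fold.

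Mitochondrial gene lists had medians slightly above 0. Nuclear-encoded oxidative phosphorylation genes had a median of 0.16 over 65 genes, all within 2-fold, with 53 above 0, at percentile 99.6. Atp5a1 and Atp5b had log2 ratios of 0.24 and 0.17. Mitochondrially encoded protein genes had a median of 0.23 over 10 genes at percentile 98.1, and mt-Co1 and mt-Nd1 had 0.23 and 0.22. The 1 gene below 0 was mt-Nd6, at -0.30 with 20577 and 16190 counts. Tricarboxylic acid cycle genes had a median of 0.26 over 25 genes, with Pcx, pyruvate carboxylase, 3.05-fold higher on 20 and 60 counts. Glycolysis and hypoxia genes had a median of -0.19 over 27 genes at percentile 2.16, with Pfkfb3, an activator of glycolysis, 2.20-fold lower. NAD metabolism genes had a median of -0.26 over 27 genes at percentile 0.79, with Ido1 5.66-fold lower on 55 and 9 counts and Parp10 2.04-fold lower. Histone and DNA demethylases and acetyltransferases had a median of -0.17 over 28 genes at percentile 0.93, with Tet2, a DNA demethylase, 2.09-fold lower. With means in place of medians, the mitochondrially encoded, glycolysis, NAD and demethylase lists no longer stood apart. Their percentiles were then 97.0, 10.0, 5.54 and 4.70.

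The lists for growth and sterol synthesis had medians slightly above 0, with most members within 2-fold. Cholesterol synthesis genes had a median of 0.38 over 21 genes, all above 0 and 3 at least 2-fold higher, among them Cyp51 and Sqle at 2.22-fold and 2.01-fold. Proliferation genes had a median of 0.32 over 34 genes, with Ccna2 and Plk1 2.20-fold and 2.10-fold higher. Cytosolic ribosomal protein genes had a median of 0.20 over 75 genes, 72 of them above 0, and Rpsa and Rps9 had log2 ratios of 0.07 and -0.15. Heat shock genes had a median of 0.22 over 16 genes, with Hspa1a and Hspa1b 2.30-fold and 2.16-fold higher. These lists had percentiles of 100, 100, 100 and 99.1. Genes of p53 and apoptosis had a median of -0.20 over 21 genes at percentile 0.64, with Trp53inp1 3.32-fold and Bcl2l1, an inhibitor of apoptosis, 2.44-fold lower.

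Pattern recognition and inflammasome genes had a median of -0.37 over 34 genes at percentile 0.00, with Tlr9, a DNA sensor, 2.29-fold lower and Clec7a, a receptor for fungal glucans, 3.38-fold higher. Chemoattractant receptor and adhesion genes had a median of -0.26 over 25 genes at percentile 0.49, which became 11.9 with means. Cxcr2 and Pecam1 were lower in that list, Pecam1 by 2.14-fold, and Cx3cr1 was higher. The remaining lists did not stand apart. NRF2 and antioxidant genes had a median of -0.08 over 25 genes, with Nqo1 3.92-fold and Slc7a11, the cystine transporter, 3.06-fold lower. Unfolded protein and integrated stress response genes had a median of -0.12 over 29 genes, with Phgdh 2.09-fold higher and Vldlr 2.03-fold lower. With means these lists passed below 2.5, at percentiles of 2.17 and 1.97. Inflammatory lipid and nitric oxide enzymes had a median of -0.14 over 22 genes, with Ltc4s, which makes leukotriene C4, 6.73-fold and Ptgs1 3.37-fold higher, and Arg2 2.54-fold lower. The percentile of 6.89 for that list became 0.72 and 0.56 with count minimums of 10 and 1. Complement and Fc receptor genes had a median of -0.17 over 14 genes, with the complement genes C1qa, C1qb and C1qc 2.67-fold, 2.37-fold and 2.28-fold higher and C3 2.06-fold lower. Immediate-early genes had a median of -0.05 over 24 genes, with Fosb and Nr4a2 2.45-fold and 2.12-fold higher and Dusp2 2.35-fold lower. Lysosome genes had a median of 0.02 over 31 genes, all within 2-fold, and Psap and Ctsb had log2 ratios of 0.12 and -0.02.

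**Figure D3:**
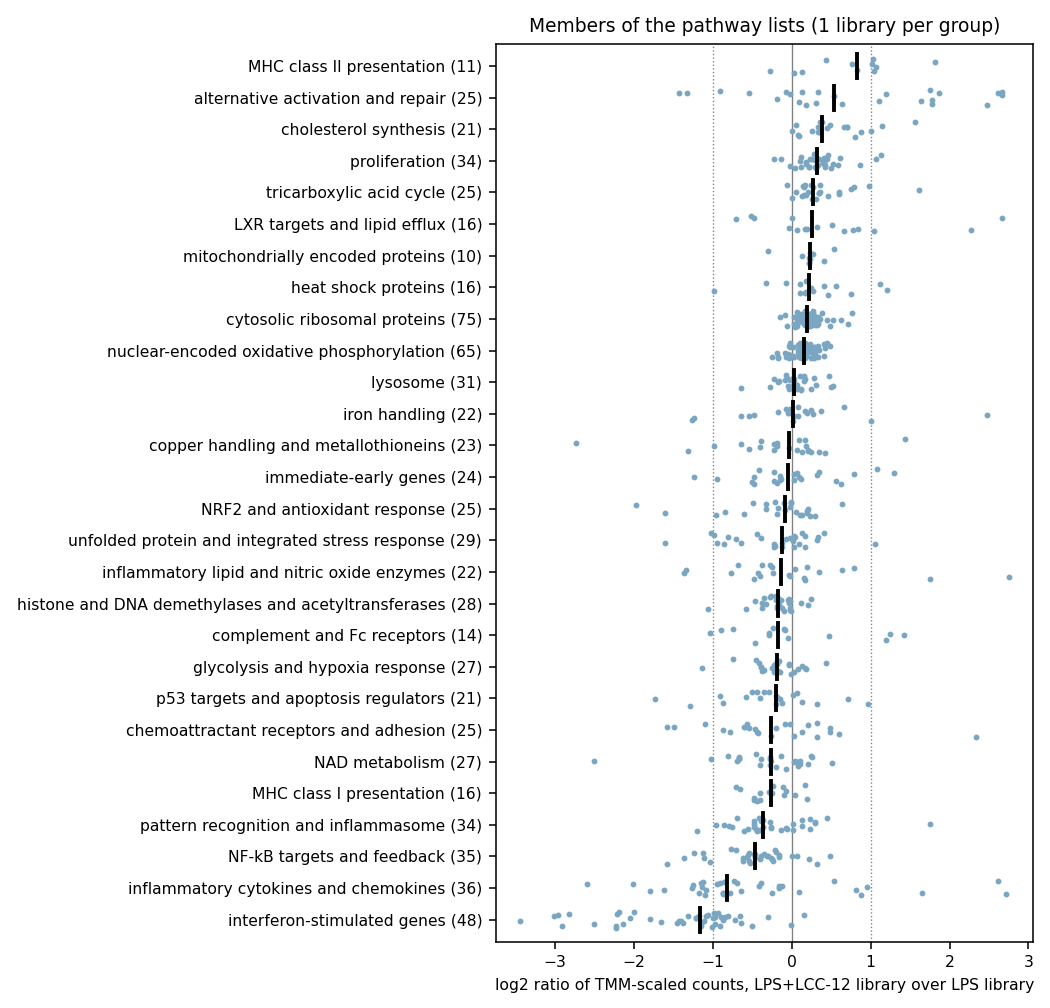
Log2 ratios of genes with 50 or more counts (points, LPS+LCC-12 over LPS) in each of the 28 pathway lists, with the list median (bar) and the number of genes in parentheses. Dotted lines mark 2-fold, and the interferon-stimulated list has the lowest median, -1.17, and the MHC class II list the highest, 0.83.

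Of the 28 pathway lists, 10 stood apart as lower and 10 as higher, where 1.4 would be outside the central 95% for random lists. Of the 10 marker lists with at least 5 genes, 5 stood apart as lower and 2 as higher, where 0.5 would be for random lists. Genes of a list can vary together, so these shares describe this pair of libraries. The medians of the copper, iron, immediate-early, lysosome and general macrophage lists lay so near 0 that their sign changed between scalings. The neutrophil and monocyte list medians of -1.14 and -0.60 apply beside each of the pathway lists.

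The 10 most abundant genes took 17.30% of counts with LPS (exact interval 17.29 to 17.31) and 19.27% with LPS+LCC-12 (19.26 to 19.28), and the 100 most abundant took 31.3% and 32.4%. Mitochondrial ribosomal RNA genes took 6.27% (6.27 to 6.28) and 7.01% (7.00 to 7.02). Mitochondrially encoded protein genes took 0.719% (0.717 to 0.722) and 0.851% (0.848 to 0.853). Their counts were very uneven, with 124382 and 141349 for mt-Co1 but 98 and 138 for mt-Co2 and 73 and 94 for mt-Co3. The share may therefore be partial, and the cause was not tested. Genes classed as ribosomal RNA took 0.0720% (0.0712 to 0.0727) and 0.0479% (0.0473 to 0.0485), and cytosolic ribosomal protein genes 1.45% and 1.69%. The predicted genes Gm26917, Gm42418 and Gm23935, singled out after their values were seen, together took 6.18% (6.18 to 6.19) and 7.16% (7.15 to 7.17), and Gm26917 and Gm42418 are known to collect ribosomal RNA reads. Protein-coding genes held 82.8% of counts with LPS and 81.6% with LPS+LCC-12.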

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

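The restriction to protein-coding genes and the neutrophil reference were chosen after seeing the data. Leaving out a replicate was not possible with 1 library per group, and no paired analysis was possible because each group has 1 library. Under the 4 other scalings, 5 added counts and thinning, both counts stayed within 1.5 times of 540 higher and 896 lower genes. Higher and lower counts were 1462 and 2387 with a minimum of 10 counts, 4143 and 6439 with 1, and 298 and 438 with 200. They were 1304 and 1794 at 1.5-fold, 195 and 340 at 3-fold, and 299 and 521 with the whole interval beyond 2-fold. These settings admit more or fewer genes by construction. Protein-coding genes alone gave 428 higher and 500 lower.

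The interferon list median was -1.13 by total counts, -1.20 by the upper quartile and -1.11 without the 100 most abundant and mitochondrial genes. It was -1.41 as a mean and -0.029 relative to the neutrophil list. The last value is a difference of 2 list medians and not a correction for the share of neutrophils. Means of the cytokine, small peritoneal and large peritoneal lists were -0.46, 1.52 and 1.18. The small peritoneal median was 1.84 without the 100 most abundant and mitochondrial genes. The neutrophil median was -1.17 by the upper quartile, -1.08 without those genes, -1.18 with a minimum of 200 counts and -1.06 with 1.

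Scalings shift all genes nearly alike and so leave percentiles in place. Of 304 percentiles under the other alternatives, 289 kept their side of the limits. With means, those of MHC class I, mitochondrially encoded, glycolysis, NAD, demethylase and chemoattractant lists moved inside, to 4.55, 97.01, 10.04, 5.54, 4.70 and 11.89, and those of NRF2 and unfolded protein lists moved outside, to 2.17 and 1.97. With a minimum of 1 count the mitochondrially encoded and NAD lists were at 97.01 and 5.2, and lipid and nitric oxide enzymes at 0.56, or 0.72 with 10. With 200 the mesothelial and fibroblast lists were at 27.30 and 13.89, with fewer genes. After thinning the chemoattractant list was at 2.63. Except where the setting changes the genes admitted, the cause was not tested. Of 852 ratios of named genes, 738 stayed inside their counting interval.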

Other observations

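Among 290 symbol stems with at least 6 protein-coding genes of 50 or more counts, grouped after the values were seen, some of the lowest and highest medians are given here as values without a test. The Ifit and Krt stems were lowest, with medians of -2.89 and -1.58, and 5 of 6 Ifit and 4 of 6 Krt genes were in fixed lists. The Slfn stem, the Schlafen genes, had a median log2 ratio of -1.44 over 7 genes, 5 of them at least 2-fold lower and none higher, and 2 of the 7 were in a fixed list. The genes named in this paragraph and the next were also chosen after their values were seen. Slfn4 had 207665 counts with LPS and 50195 with LPS+LCC-12 (log2 ratio -2.00, -2.02 to -1.99). The Ifi stem, interferon-inducible genes, had a median of -1.03 over 16 genes with 9 lower, among them Ifi208 at -2.66 and Ifi214 at -2.39. Of these 16 genes, 5 were in fixed lists. The Ceacam stem had a median of -1.35 over 6 genes with 4 lower and 1 higher. The Col stem, collagens apart from Col4a3bp, had a median of -1.09 over 19 genes with 11 lower and 2 higher, and 3 of the 19 were in fixed lists. The fibroblast and mesothelial marker lists had medians of -0.91 and -1.99 in the same libraries. Besides Col6a3, the collagen VI genes Col6a1 and Col6a2 had 58 and 23 counts and 73 and 13 counts. The Serpinb stem had the highest median, 0.95 over 6 genes with 3 higher. The Cacna stem, calcium channel subunits, had a median of 0.87 over 6 genes with 3 higher, led by Cacna1a at 1.86 (1.76 to 1.97).

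Il18r1 had 2298 and 383 counts (log2 ratio -2.54), Il18rap had -1.73 and Il1r2, a decoy receptor, had 29970 and 8194 counts (-1.82). Ednrb, the endothelin B receptor, had 2047 and 11019 counts (2.47, 2.41 to 2.54), and Cbr2 had 359 and 2439 counts (2.81). Dmwd, which ends at position 19082776 of chromosome 7, upstream of Dmpk on the same strand, had 85 and 418 counts (2.34, 2.00 to 2.70). Jchain, which joins chains of IgA and IgM, had 36 and 3 counts (-3.34, -5.88 to -1.88), next to the lower Igha.

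All tests in the following paragraphs were chosen after the results were seen. The treatment with LCC-12 and chance differences between the pools remain open for each pattern and could not be separated with 1 library per group.

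The lower interferon-stimulated genes were set against the scaling and against a lower share of neutrophils. The scaling is argued against, because a scaling error would move all genes alike, whereas the list median lay below the median of all genes by a log2 difference of -1.19. A lower share of neutrophils remains open, although the sort was for small peritoneal macrophages and is meant to leave other cells out. The interferon list median minus the neutrophil median was -0.029, while 23 of 48 interferon genes had their whole interval below that median and 5 had it below the lowest neutrophil marker. The level of these genes per cell type is not known here, and some neutrophils may carry more of them than others.

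The higher genes of the small and large peritoneal macrophage lists were set against shifts in the cells sorted. A larger macrophage share would also raise genes that only macrophages carry. The general macrophage list had a median of 0.033. Its upper quartile, 0.39, lay below the lower quartiles of the small and large peritoneal lists, 0.73 and 0.48. General macrophage genes thus did not rise with the peritoneal lists. Other sorted cells, such as monocytes, may also express them, so these values do not decide on a larger macrophage share. More large peritoneal macrophages with fewer recruited cells remains open, although the sort was for small peritoneal macrophages and is meant to leave large ones out. The monocyte and neutrophil list medians of -0.60 and -1.14 go with it. The small peritoneal and monocyte-derived list had a lower quartile of 0.73 and 14 of 15 genes above 0. That list shares 5 genes with the MHC class II list and 4 with the alternative activation list. Such genes can differ in content per cell, so its values do not decide on the share of recruited cells. Gata6 at 0.49 and Ccr2 at -0.02 were within 2-fold. Of 20 large peritoneal markers, 4 had the list median inside their counting interval, but differences in content per cell could give such a spread. The intervals cover counting error only, so that number does not decide.

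The lower markers of neutrophils, mast cells, mesothelium and fibroblasts were set against a purer sort that lowers the markers of every other cell type alike. That even form is argued against by the B cell list, whose median lay 1.35 above the neutrophil median on the log2 scale. Ighm had 4800 and 5090 counts, although Igha, Ighv1-55 and Jchain were lower. A sort that removed some cell types more than others was not tested and remains open. Fewer neutrophils with unchanged content remains open. For 11 of 15 neutrophil markers the counting interval left out the list median, from Mmp8 at -2.31 to Camp at -0.12. Such intervals cover counting error only and are narrow at high counts, so this number does not decide. Monocytes and macrophages may also express some of these markers.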
